A study of Mus musculus with 4 samples.

How the data were processed

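RNA bound by DHX9 was measured by FLASH in neural progenitor cells grown from WT26 embryonic stem cells, in 2 libraries with an antibody to DHX9 and 2 with rabbit IgG. Per the labels' protocols, cells were irradiated with ultraviolet light, lysed and sonicated, and the protein was pulled down on beads. After a brief RNase I digestion, barcoded adapters were ligated to the RNA. One barcode told the antibodies apart and another the biological replicates, and random bases served to merge PCR duplicates. IgG and DHX9 samples were mixed after adapter ligation, and the pooled cDNA was sequenced in paired-end mode on a NextSeq 500. Groups were taken from the sample titles.

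The authors deposited 1 peak list for the series, which per the file itself was made with PEAKachu, a peak caller for crosslinking data that compares pull-down with control libraries. Each of its 43106 lines gave a chromosome, a start, an end and a strand. The deposited positions are 1-based bases of the genome, and the list's columns for a score and a frame were empty. Per the submitters' processing notes, Bowtie2 2.2.6 was used and the builds hg19 and mm10 were named. The peak caller's version, settings, normalization and threshold were not given in the sources used here, nor was the handling of reads that map to several places. Whether duplicates were merged before the peaks were called is stated only as the purpose of the random bases, per the labels' protocols. Reads in repeats, paralogs and nested genes can therefore be placed by rules that are unknown. With 1 list from 4 libraries there was no count, depth or score per library or peak, so no replicate could be left out, no pairing by replicate letter was tested, and no counting error could be given.

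The peaks were read as mm10 coordinates, because mm10 is the mouse build of the pair named. This was checked by moving all peaks by 5 Mb: the number in an annotated gene fell from 42070 to 20279, and 4 of the unmoved peaks lay beyond the last gene of their chromosome. Genes came from a RefSeq table of the assembly GRCm38.p6 (mm10), of which 49980 genes with a chromosome were used, 21900 of them protein-coding. The table gave gene spans and kinds of gene, without strand, exons or sequence. A peak belonged to every gene whose span held its midpoint, and the text gives the number that lay in no other gene. Genes that overlap are uncertain where their strands are unknown.

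The design, the 12 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Several planned results needed a genome sequence, exons or gene strand, which were not used here: the shares of peaks in introns and in 3' untranslated regions, the shares on the short interspersed elements B1 and B2, and the odds by orientation of B1 elements and by inverted neighbours. The comparison of the caller's own value between peaks was also left out, as the list holds none. The planned share of peaks on the gene's own strand was replaced by the share on the strand that holds most of the gene's peaks. That share is above 50% by construction, so it was compared with random strands in the same genes. The question raised by the series title, about RNA from Alu elements, could thus not be addressed.

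The named genes were the 15 with the most peaks on their majority strand, the 10 with the most such peaks per kb among genes with at least 10, up to 4 members with the most peaks of each list, and Xist and Dhx9. Some genes that this rule takes are not reported here or plotted. Other genes named for strand, for having no peak, as overlapping neighbours or in the closing section were chosen after their values were seen.

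Strands were compared with 100000 draws of random strands. Spacing was compared with 1000 placements of each peak in its gene, with 500 bootstrap draws over genes for the interval. The X was compared with the autosomes by 100000 permutations of genes within 10 length deciles. Each list was set against 10000 random lists matched on length decile, drawn from protein-coding genes, or from long noncoding genes for the noncoding list. The p-values of the 12 lists were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Other intervals are 95% bootstrap intervals from 2000 draws. Of the double-stranded RNA list, Rigi was listed in the table under its older symbol, Ddx58, and was counted once. Genes near each other are not independent, so intervals over genes can be too narrow; for single chromosomes, the intervals used blocks of 5 Mb, while the p-values came from permuting genes.

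Alternatives were the longer part of the peaks (at least the median length), merging of peaks within 50 bases, any overlap of at least 1 base with a gene, protein-coding genes only, 50 length bins in place of 10, at least 3 peaks per gene, and the X without Xist and genes overlapping it. Added after the data were seen were moves of each peak by up to 10 kb, leaving out genes with 50 or more peaks, leaving out the mitochondrial genome for strand, leaving out predicted genes and sensory receptor families, and leaving out chromosomes 8 and 11, and for these chromosomes other matching.

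The code was tested on simulated data. For the strand comparison over 21900 genes, random strands gave 58.97% against 59.01% by chance, and 97.9% was returned where 2% of strands had been turned. For spacing, uniform peaks gave a ratio of 0.992 and clusters of 3 gave 0.0989. For the X, 40 sets without an effect gave a median ratio of 0.972, with 7.5% of sets under the threshold, and thinning X peaks to a ratio of 1 in 3 gave 0.320 with 100% called. Random lists were called in 0% of cases, and 87.5% of 40 lists with 12 of 25 members drawn among genes with a peak were called. For chromosomes, 0% were called without an effect, and chromosome 8 raised 1.4-fold was called in 90% of 10 sets, with a median ratio of 1.38. The X and chromosome sets shuffled genes independently, so they do not show how often likeness between neighbouring genes gives false calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.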

Results

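The series mapped the RNAs bound by DHX9, an RNA helicase that unwinds double-stranded RNA, in mouse neural progenitor cells. The cells were grown from WT26, a male embryonic stem cell line of mixed C57BL/6 and 129 background. Binding was mapped by FLASH, a form of crosslinking and immunoprecipitation sequencing in which ultraviolet light fixes protein to RNA and the RNA pulled down with an antibody is sequenced with its strand. There were 2 groups, DHX9 antibody and rabbit IgG as background, each with 2 biological replicate libraries (A and B). The data analysed here were 1 list of peaks for the 4 libraries together, so no value per library entered any comparison, the sequencing depth was unknown, and replicate error could not be computed. Intervals and p-values below come from resampling genes or peaks within that list and leave out the variation between replicates. A gene without a peak is a gene without a called peak, since expression and depth were not measured here.

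The first question was what RNA the DHX9 peaks covered. The list held 43106 peaks with a median length of 153 bases. The lengths ran from 16 to 981 bases, with the middle part between 122 (25th percentile) and 201 (75th percentile). The plus strand carried 22930 peaks and the minus strand 20176. An annotated gene span held the midpoint of 42070 peaks (97.6%), and a protein-coding gene held 41093 (95.3%). After all peaks were moved along their chromosomes by 5 Mb, only 20279 (47.0%) lay in a gene, so the share in genes depended on the peaks' positions. No other build was compared. Of 21900 protein-coding genes, 4133 (18.9%) carried at least 1 peak. Of 12727 long noncoding RNA genes, 419 (3.29%) did, and 799 of the 2641 peaks in them lay in no other annotated gene. Among small RNA genes, 93 small nucleolar RNA genes held 94 peaks, of which 2 were in no other gene. Of the 44 peaks in 42 transfer RNA genes, 34 were in no other gene, and of the 20 in small nuclear RNA genes, 11 were. The 42 transfer RNA genes included some of the mitochondrial genome, where peaks lay on both strands. Both Y RNA genes had a peak in no other gene.

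Peaks were concentrated in few genes. The median protein-coding gene with a peak had 4, while 1057 genes had exactly 1, 137 genes had 50 or more and 44 had 100 or more. The 100 protein-coding genes with the most peaks held 29.1% of all pairs of a peak and a protein-coding gene. Longer genes carried peaks more often: 0.868% of genes in the shortest length decile (median span 0.942 kb) and 39.7% in the longest (median span 184.8 kb). Per Mb of gene span the relation was not monotonic, with 16.9 peaks per Mb in decile 1, 71.5 in decile 7 and 28.2 in decile 10.

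The most peaks lay in Npas3, a neural transcription factor gene (chromosome 12, 53248026 to 54072173, mm10), which carried 661 plus-strand peaks over 824.1 kb. Of these, 465 lay in no other annotated gene and 151 also lay in the predicted noncoding gene Gm51419. Maml2, which encodes a Notch coactivator, followed with 374 peaks on chromosome 9. The nuclear factor I genes Nfia and Nfib, both on chromosome 4, held 339 and 206. For Nfib, 129 of the 206 peaks could equally be counted for 2310067E19Rik, a noncoding gene within it. The adhesion or receptor genes Adgrb3 (307 peaks), Kirrel3 (287), Grm5 (286) and Pcdh9 (253) were also among the 15 genes with the most peaks. So were the transcription factor genes Zeb1 (287) and Tcf4 (197), together with Auts2 (281), the kinase gene Map4k4 (267) and the scaffold gene Grip1 (205). Map4k4 was the densest of the 15, with 2.13 peaks per kb over 125.4 kb, followed by Airn (1.64 per kb) and Zeb1 (1.56 per kb).

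**Figure D1:**
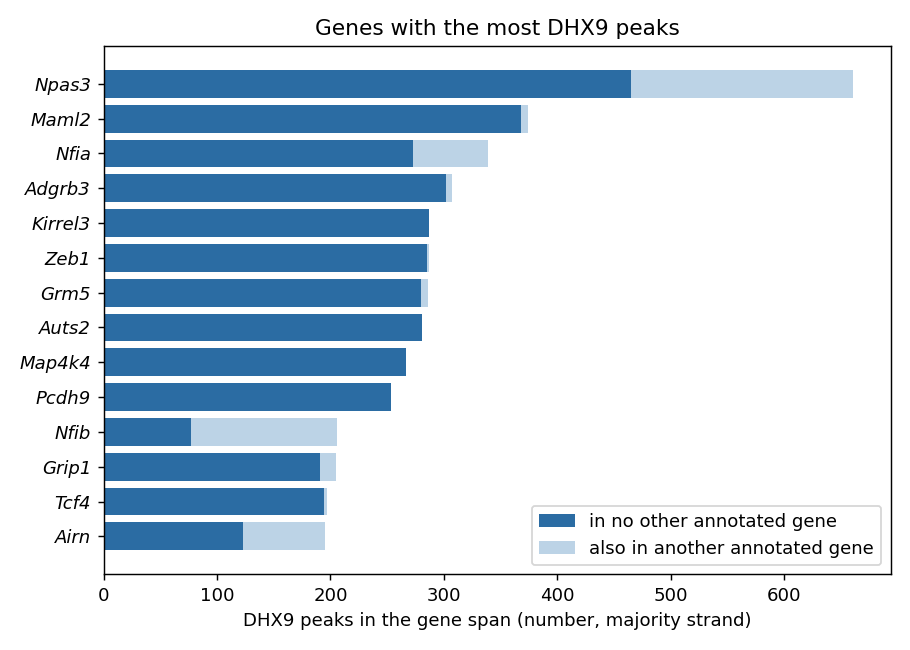
Number of DHX9 peaks (horizontal axis) in genes with the most peaks on the strand that held most of the gene's peaks; dark bars are peaks in no other annotated gene and light bars are peaks that also lie in another one. Npas3 leads with 661 peaks, and most of the 206 peaks of Nfib lie in another gene as well. The counts come from 1 peak list and have no error bars.

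The only noncoding gene among these 15 was Airn, an imprinted RNA transcribed antisense to the insulin-like growth factor receptor gene Igf2r. Airn (chromosome 17, 12741311 to 12859884) held 195 plus-strand peaks, 68 of them where it overlaps Igf2r and 127 outside that overlap. The minus strand had 1 peak at this locus, in the part of Igf2r that Airn does not overlap.

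**Figure D2:**
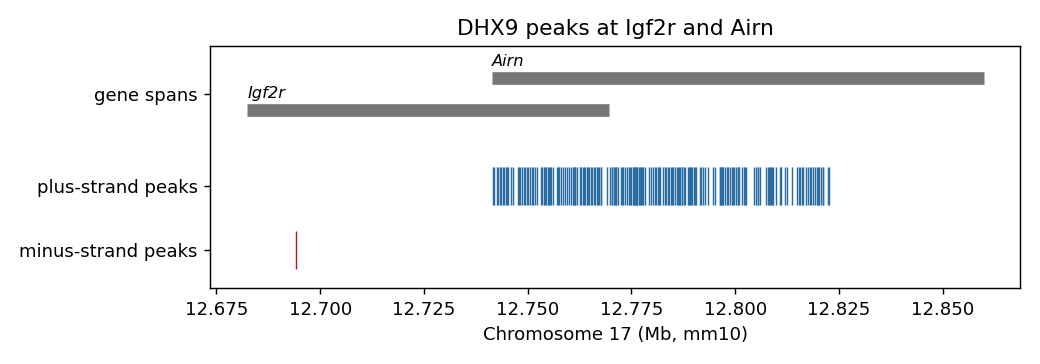
Midpoints of DHX9 peaks on each strand (short vertical lines) along the part of chromosome 17 that holds Igf2r and Airn (mm10, in Mb), with both gene spans as grey bars. The 195 plus-strand peaks lie within the span of Airn, and the single minus-strand peak lies in the part of Igf2r that Airn does not overlap.

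By density, the highest values among genes with at least 10 peaks were 2.82 peaks per kb in Gm51419 and in Igfbp2, which encodes an insulin-like growth factor binding protein. Igfbp2 held 79 peaks over 28.0 kb of chromosome 1 (72824480 to 72852474), all in no other gene. Gas5, a host gene of small nucleolar RNAs, had 11 peaks (2.79 per kb), 3 of them in no other gene. Spry4, an inhibitor of receptor tyrosine kinase signalling, had 42 (2.78 per kb), Arl8a 23 (2.44 per kb) and Fscn1, which encodes an actin bundling protein, 28 (2.18 per kb), all in no other gene. The remaining dense genes shared every peak with another gene: 2310067E19Rik (129 peaks, within Nfib), LOC115486929 (19, within Gpm6a), Gm19417 (63, within Nfia) and Rbm4b (22, within Gm21992). Rbm4b also has a close paralog, Rbm4, with 15 peaks, so the split between these genes is uncertain.

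The 12 gene lists asked which functional groups the bound RNAs came from. Genes for splicing and RNA processing were covered most completely, with 30 of 32 members (93.8%) carrying a peak. Random protein-coding genes of like length gave 18.3% (middle 95% of random lists, 6.25 to 31.25%). Rbm25 had 61 peaks, Rbm39 58, Hnrnpc 38 and Sfpq 36. Of the chromatin regulators, 21 of 27 (77.8%) had a peak against 31.8% by chance (14.8 to 48.1%), led by the DNA methyltransferase gene Dnmt3a (63 peaks), Arid1a (54) and Smarca4 (50). Of the neural progenitor genes, 15 of 25 (60%) had one against 19.5% (8 to 36%), including the glutamate transporter gene Slc1a3 (122), Ptprz1 (64), Nfia and Nfib. The other 10 members, Sox2, Pax6 and Nes among them, had none. Ribosomal protein genes, which are short, had a peak in 16 of 35 (45.7%) against 4.47% (0 to 11.4%), but none reached 10 peaks. That share was 20% against 3.01% with the longer peaks and 22.9% against 1.93% with at least 3 peaks per gene. Rpl23 had 9 peaks and Rpl5 had 7. All 4 peaks of Rpl13a and all 4 of Rpl7a also lay in other annotated genes, which for Rpl13a are small nucleolar RNA genes. Of the nuclear long noncoding genes, 10 of 20 (50%) had a peak against 4.22% of random long noncoding genes (0 to 15%), with Airn, Pvt1 (52), Kcnq1ot1 (44, all within Kcnq1) and Gas5 in front. Without predicted genes in the background, the random share for this list was 15.4% (0 to 30%; adjusted permutation p = 0.00144). In the main comparison the adjusted permutation p over the 12 lists was 0.00048 for each of these 5, from a raw p of 0.0002, which is the smallest that 10000 random lists can give. Expression could not be matched, so the comparison does not separate binding from how strongly a list is expressed.

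Cell cycle genes had a peak in 11 of 25 members (44%) against 18.5% by chance (4 to 36%; adjusted permutation p = 0.0084). Ccnd2, a D-type cyclin gene, held 55 peaks and the topoisomerase gene Top2a 29, followed by Kif11 with 5 and Ccnd1 with 3. This call was lost when only peaks at least as long as the median were used (32% against 13.8% by chance), when at least 3 peaks were required (24% against 10.8%), and without chromosomes 8 and 11 (36.4% against 17.5%). The fold over chance was 2.37 in the main comparison and 2.31, 2.22 and 2.08 in these settings.

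The other 6 lists did not pass the threshold. Double-stranded RNA binding and editing genes had a peak in 10 of 19 (52.6%) against 29.9% (adjusted permutation p = 0.0876). Dhx9 itself held 32 minus-strand peaks (chromosome 1, 153455756 to 153487688), Zfr 29 and Dgcr8 12, while the RNA editing gene Adar had none. In the list named long neural adhesion, 13 of 22 members (59.1%) had a peak against 39.7% (adjusted permutation p = 0.139), among them Auts2, Lsamp (138) and Gpc6 (20). The name is a label, since not all members, Auts2 among them, are adhesion genes. Mature neuron genes had a peak in 1 of 17 (5.88%), namely Map2 with 46, against 28.9% (raw permutation p = 0.042, adjusted 0.072). None of the 16 pluripotency genes had a peak, where chance gave 12.3% (adjusted permutation p = 0.256). No count could have been lower, so the test could not have called this list depleted. Lists of markers of other cell types the culture could hold lay near chance, which does not show that such cells were absent. Astrocyte and oligodendrocyte genes had a peak in 3 of 16 (18.8% against 20.7%): Cnp with 8, all shared with Dnajc7, Olig1 with 4 and Pdgfra with 1. Mesoderm, endoderm and fibroblast genes had one in 3 of 17 (17.6% against 21.8%): Col3a1 with 28, Col1a1 with 7 and Col1a2 with 2. The adjusted permutation p was 1 for both.

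**Figure D3:**
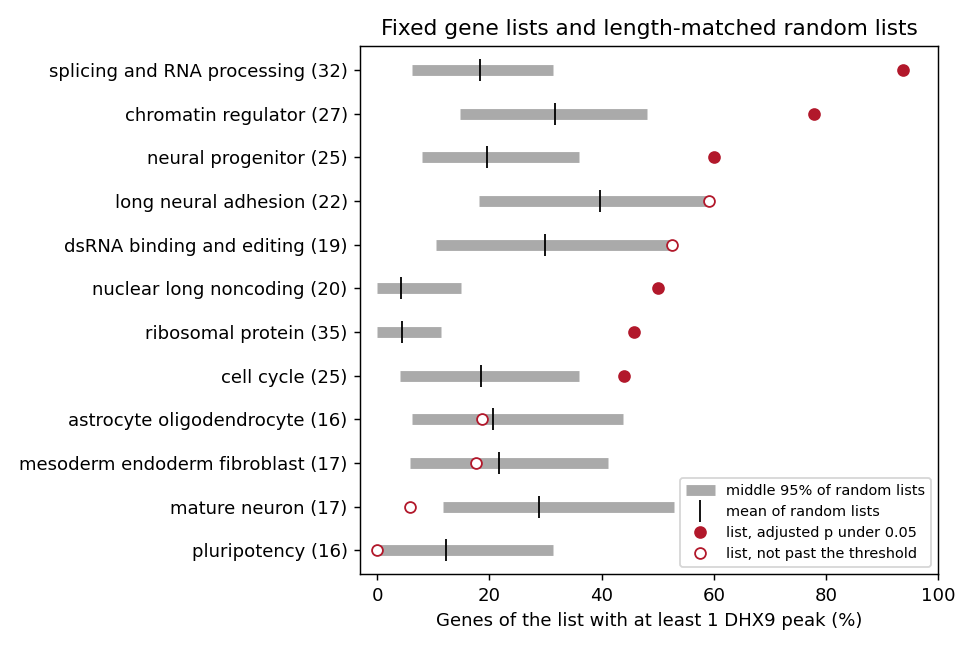
Percentage of each fixed gene list with at least 1 DHX9 peak (circles; the number of members is in brackets) beside the mean (black tick) and middle 95% (grey bar) of 10000 random lists matched on gene length. Filled circles are the 6 lists with an adjusted p under 0.05, from cell cycle at 44% to splicing and RNA processing at 93.8%.

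Each gene's peaks lay almost always on a single strand. In the 2967 genes with at least 2 peaks that lay in no other gene, 38323 of 38393 peaks (99.8%, 95% interval over resampled genes 99.8 to 99.9%) were on the strand that held most of the gene's peaks. Strands drawn at random gave 59.2% on average (permutation p = 2e-05, the smallest that 100000 draws can give, two-sided). The 2967 genes included mitochondrial ones, which held 17 of the 70 exceptions, with 4 of 8 such peaks in COX1 and 3 of 8 in ND5. Among nuclear genes, the exceptions included 5 of 29 peaks in Phykpl, 3 of 6 in Gabpb1 and 3 of 7 in Prr14. All 5 genes were chosen after their values were seen. The 5 Mb move left this share at 94.4%, so it also measures that neighbouring peaks share a strand wherever genes are annotated. The gene's own strand was not used here.

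Peaks clustered within genes. The median distance between the midpoints of neighbouring peaks of a gene and strand was 486 bases (95% interval 474 to 501; 35349 distances in 2950 genes). For peaks placed at random in the same genes, the median distance averaged 1659 bases (lowest and highest of 1000 placements, 1623 and 1692). This makes a ratio of 0.293 (permutation p = 0.002, the smallest that 1000 placements can give, two-sided). Distances under 500 bases made up 51.1% of the observed distances and 21.9% of those from 1 random placement. Distances above 10 kb made up 6.21%. Placed peaks were allowed to overlap, and exons were not told apart from introns. Only peaks in no other gene were used, but they were placed over the whole span, including stretches shared with other genes. This can widen the placed distances. With protein-coding genes only, where noncoding genes do not remove peaks, the ratio was 0.303.

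**Figure D4:**
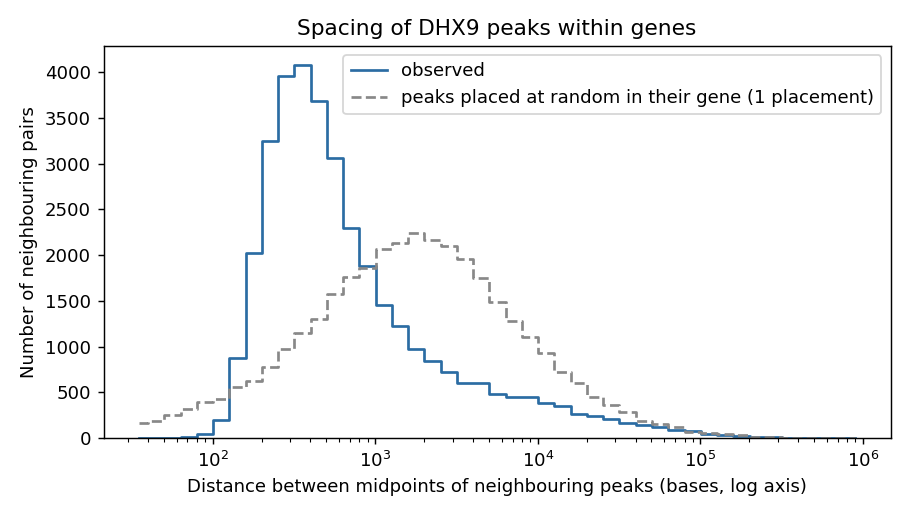
Number of neighbouring peak pairs by the distance between their midpoints (bases, log axis), for the observed peaks (solid) and for 1 random placement of the same peaks in their genes (dashed). The observed distances have a median of 486 bases, while the medians of all placements average 1659 bases.

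The X chromosome was compared with the autosomes because the fly relative of DHX9, MLE, acts in X chromosome dosage compensation. X-linked protein-coding genes carried fewer peaks: 16.5 per Mb of gene span (761 peaks, 966 genes) against 41.2 per Mb on autosomes (41253 peaks, 20665 genes). The ratio was 0.402 (95% interval over resampled genes 0.271 to 0.580). It lay outside the middle 95%, 0.641 to 1.3998, of ratios from genes permuted between X and autosomes within length deciles (permutation p = 2e-05, the smallest that 100000 draws can give, two-sided). A peak was present in 116 of the X-linked genes, where permutation gave 170.2. Matching on local gene density as well as length gave 157.8 expected genes, a ratio of 0.735 (95% interval over blocks 0.576 to 0.895). This ratio counts genes with a peak, not peaks per Mb. By the same measure, autosomes 7 (0.809), 9 (0.851) and 14 (0.809) were also called lower than expected. Xist, the noncoding RNA that silences an X chromosome in female cells (chromosome X, 103460373 to 103483233), had 0 peaks, in a cell line labelled male. Male cells have a single X, and the values were not corrected for the number of copies or for expression. The X had the lowest density of the 20 chromosomes compared, and the autosomes themselves ranged from 21.7 per Mb (chromosome 13) to 82.8 (chromosome 11). The permutation took genes as independent and there is a single X, so the permutation p does not measure the spread between chromosomes.

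**Figure D5:**
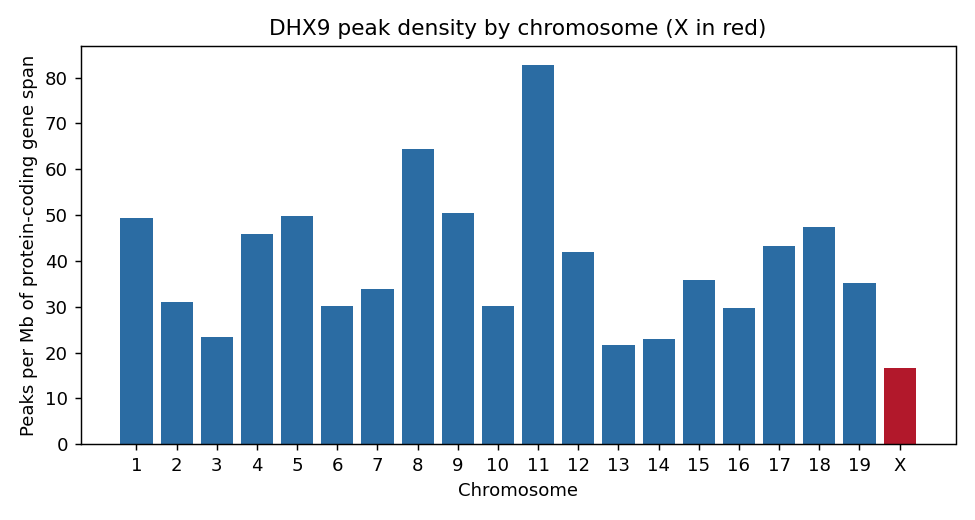
DHX9 peaks per Mb of protein-coding gene span on each autosome (blue) and on the X (red), counted from 1 peak list, without error bars. The X has the lowest bar, at 16.5 peaks per Mb, and chromosome 11 the highest, at 82.8.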

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

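The counts in this part were looked up after the peak list had been seen, and none was compared between groups. They are peaks on the mitochondrial genome, on unplaced sequence or in no annotated gene, and a signal in places that most comparisons leave out is what drew attention to them. Mitochondrial genes did enter the strand and spacing comparisons; on nuclear chromosomes only, the majority-strand share was 99.9%.

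The mitochondrial genome carried 52 peaks, 22 on the plus strand and 30 on the minus strand. They covered 6888 bases on the plus strand and 6857 on the minus strand, of which 4196 were covered on both. The longest stretch without a peak on either strand ran from base 6553 to base 10805. COX1 held 4 peaks on each strand. Sequence not placed on a chromosome carried 6 peaks. Peaks with no annotated gene at their midpoint numbered 1028 on the nuclear chromosomes, and their place relative to the nearest gene is weighed under the other observations. Peak calling already compared the DHX9 libraries with IgG, and no IgG level for these positions was used here.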

How the results depend on the processing

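Settings that leave out chromosomes 8 and 11, the mitochondrial genome, genes with 50 or more peaks, or predicted genes and receptor families, and moves of up to 10 kb, were chosen after seeing the data. Keeping only peaks at least as long as the median left 21796 of the 43106 peaks, by construction. The cell cycle list (44%) lost its call with those peaks (32%, adjusted permutation p = 0.0564), with at least 3 peaks per gene (24%, p = 0.16) and without chromosomes 8 and 11 (36.4%, p = 0.0823); the fold over chance was 2.37 in the main comparison and 2.31, 2.22 and 2.08 in these, with fewer peaks or genes counted in each. A pair of lists that never passed the threshold (adjusted permutation p = 1 here) moved from below to above chance: astrocyte and oligodendrocyte genes with the longer peaks (18.8% against 15.5%) and with at least 3 peaks (12.5% against 12.3%), and mesoderm, endoderm and fibroblast genes with the longer peaks (17.6% against 16.4%); the cause was not tested. The other 105 tested values for strand, spacing, gene lists and the X kept their direction and side of the threshold under the alternatives run. Many of these values could hardly change. Merging, any overlap and protein-coding genes only left the number of members with a peak the same in every list compared. Others belong to lists that passed the threshold in no setting. Calls for single chromosomes, which changed more, are under the other observations. The X to autosome ratio ranged from 0.339 to 0.518, spacing over placed spacing from 0.279 to 0.490, and the majority-strand share from 99.8 to 99.9%. For the X, 2 of the alternatives moved nothing. Only protein-coding genes were used anyway, and leaving out Xist, a noncoding gene, and genes that overlap it removed none of the 966 X-linked genes. Of 59 named genes, the longer peaks changed the peak count by over 1.5 times for 42, largely because that setting drops so many peaks. Merging did so for 4.

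Not run, for want of exons, sequence, gene strand or a value per peak, were the alternatives for introns, 3' untranslated regions, B1 and B2 elements and the caller's own value. No paired analysis was possible because the peak list carries no value per library, although DHX9 and IgG libraries share replicate letters. For the same reason no replicate was left out, and what depth limits is unknown: a gene without a peak was not told apart from a weakly expressed one.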

Other observations

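The tests on chromosomes 8 and 11 and on peaks split by the caller were chosen after those results had been seen, and the genes and regions in the first paragraph were chosen after their values were seen.

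Some imprinted noncoding RNA genes other than Airn carried peaks, and others had few or none. Kcnq1ot1 (chromosome 7, 143213111 to 143296547) had 44 minus-strand peaks, and the surrounding protein-coding gene Kcnq1 had none beyond those 44. At the Gnas locus on chromosome 2, the Gnas span held 18 plus-strand and 23 minus-strand peaks. The overlapping Gnasas1 span held 30 minus-strand peaks, of which 7 lay in no other gene, and another 35 minus-strand peaks lay beside it, between 174267100 and 174280840, in no annotated gene. Snhg14 held 8. Among the other imprinted noncoding genes looked up, Meg3 had 1 peak, and Rian, Mirg and Peg13 had 0. On chromosome Y, 26 of 41 peaks lay in Uty and 2 in Eif2s3y, while Kdm5d and Ddx3y had 0. The largest group of peaks in no annotated gene lay on the plus strand of chromosome 16, with 81 peaks between 77601121 and 77690536 and another 21 between 77562981 and 77599930. The annotated gene nearest to the 21 peaks was Mir99ahg, a microRNA host gene with 39.

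Genes with a peak were over-represented on chromosomes 8 and 11: on chromosome 8, 297 genes had one against 205.3 expected from gene length and local gene density, a ratio of 1.45 (95% interval over 5 Mb blocks 1.23 to 1.65), and on chromosome 11, 391 against 306.9, a ratio of 1.27 (1.12 to 1.45; adjusted permutation p = 0.001 for both). The permutation takes neighbouring genes as independent and called 4 of the 20 chromosomes higher and 4 lower, but the block intervals of chromosomes 5 (0.878 to 1.34) and 18 (0.989 to 1.32), both called higher, hold 1, and under the alternatives chromosomes 5, 14 and 18 lost a call and 1, 13 and 19 gained one, while 8 and 11 stayed called higher in each. The matching argues against length and density as the whole cause. Extra copies of chromosomes 8 and 11, which mouse embryonic stem cell lines are known to gain in culture, stay open as a hypothesis. Such copies were expected to raise both parts of a chromosome, with intervals above 1. The second part of chromosome 8 had 1.62 against 1.10 (0.886 to 1.32) in the first. The first part of chromosome 11 had 1.63 against 1.12 (0.983 to 1.28) in the second. The intervals of the lower parts hold 1, so that expectation was not met on either chromosome. The parts differed by 1.47 (1.15 to 1.90) and 1.46 (1.15 to 1.80). Parts of other chromosomes differed by up to 1.36, so the test does not decide. An earlier form of this test, which asked only whether the intervals of the parts overlap, would have excluded extra copies as the whole cause and was replaced because gene content alone can make parts differ; expression was not measured, and no biological explanation was tested.

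The close spacing of peaks was set against a pair of technical explanations. If the caller had split bound stretches into peaks at most 50 bases apart, merging these would bring the ratio of observed to placed spacing near 1. It was 0.314, so splitting at that distance does not account for the pattern. Merging left 30210 distances between neighbouring peaks, against 35349 before, so most gaps were wider. Stretches split at wider gaps would not be joined, so splitting there was not tested. Uneven signal along genes on a scale above 10 kb was tested by moving each peak at random by up to 10 kb, which gave 0.490, so it may account for part of the clustering but not for all of it. Clusters on a shorter scale, as pairs of inverted repeats or exons might give, stay open, because sequence and exons were not used here. No biological explanation was tested.

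Peaks were unevenly placed along and beyond genes. In 979 protein-coding genes with at least 10 peaks, the mean relative position over genes was 0.417 (95% interval 0.406 to 0.428). Here 0 is the start and 1 the end on the majority strand. Averaged over genes, 13.5% of a gene's peaks lay in the first 10% of its span and 5.16% (4.47 to 5.88) in the last 10%. The low share at the end argues against a bias towards 3' ends in these genes. Genes with fewer than 10 peaks were not examined for it. The mean position would also follow from more signal from unfinished transcripts, which was not told apart from binding itself. Of the 1028 peaks outside genes, 359 had no gene with peaks within 20 kb. Of the 550 that lay within 20 kb of a gene with peaks and on its strand, 80.7% were downstream of it (71.2 to 88.6 over resampled genes), consistent with RNA that continues past the annotated end for those 444 peaks; another 119 lay on the other strand. No biological explanation was tested.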
